A study of Mus musculus with 6 samples.

How the data were processed

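Total RNA was measured in 6 samples of cultured mouse aortic smooth muscle cells, 3 labelled siEzh2 and 3 labelled control, from stranded mRNA libraries (TruSeq Stranded mRNA). Each sample had 1 table of FPKM values per gene, deposited by the authors and named as FPKM per the file headers. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq, Cufflinks and the genome build mm10, without versions or the order of use. Whether the counting used the strand of the reads is not given in the sources used here, so values of genes that overlap a gene on the opposite strand are uncertain, and near-identical copies could have shared reads. The sequences of the siRNAs are not given in the sources used here either.

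The planned test was for counts. The files held FPKM, not counts, so the test planned for normalized values was used. Genes with a mean of at least 1 FPKM in at least 1 group were tested with limma 3.58.1 in R 4.3.3 (trend and robust off, no covariate) on log2(FPKM + 1). A log2 fold change on this scale, siEzh2 minus control, understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. SD and fold ratios are of FPKM. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

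All 6 tables listed the same 27502 genes, of which 35 IDs shared a symbol with another ID. GENCODE M21, on the same build, held 27434 of the IDs (99.8%), and 97.3% of these had the same symbol. Coordinates, exon overlaps, gene classes and 3′ UTRs were taken from it. FPKM values multiplied by the total exon length moved in equal steps, from which reads were recovered. Between 98.4% and 98.5% of the values under 1000 reads came out whole, within 0.02 of a read. The sums ranged from 16080006 to 18753125 reads per sample. At these depths 3 reads, the upper limit that a count of 0 allows, equal 0.16 to 0.187 CPM, a limit that covers counting error only.

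A fixed set of 41 gene lists, with 1316 genes together, was tested with limma's camera (preset correlation 0.01, two-sided) on the same values. Of these, 37 had at least 5 tested members, over which p-values were adjusted. Camera with an estimated correlation and fry, which tests whether the members of a list move on balance 1 way, were alternatives. The named genes were Ezh2, Ezh1, Eed and Suz12, then the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 FPKM and no overlap between groups, without predicted genes and pseudogenes. Rises and falls were ranked by the log2 fold change on log2(FPKM + 1). The 3 tested members with the smallest p in each list were added, of which the text prints some. Other genes are said to have been chosen after their values were seen. The lists, this rule, the tests and all alternatives but the last 2 given here were fixed before the data were examined.

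The test was tried on simulated data for this comparison, with 11608 genes tested and 50 genes changed at each size. It called 64% of genes changed 1.25 times, 94% of those changed 1.5 times and 100% of those changed 2 or 3 times. Of 217 calls 14 (6.45%) were false, with calls in a further list of changed genes counted as true. Far fewer genes were changed than were called in the real data. All shared 1 dispersion (spread between replicates, 0.000762), so these rates may not carry over. The changed list was called and 0 of 20 unchanged lists were. Simulated genes varied independently, so this did not try the list test on correlated members. In the real data the estimated correlation was 0.123 for interferon-stimulated genes and 0.138 for G2/M and mitosis genes. For chemokines it was 0.0439 and for contractile genes 0.0295. It was below the preset 0.01 for G1/S genes (0.00493), mitochondrially encoded genes (0.00238), antioxidant genes (−0.0147) and adipocyte markers (−0.0791). These lists also lost their calls with an estimated correlation, so a higher correlation does not account for their loss. Pairs of samples were also compared on recovered reads. The chi-square per degree of freedom was 2.14 to 3.29 within groups and 27.9 to 30.0 between groups, so no sample was a copy of another.

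Alternatives were quantile normalization, no filter, a filter on recovered reads, the replicate number as a block, limma with trend and robust on, a pseudocount of 0.1, a minimum log2 change of 1 and leaving out each sample in turn. A limma-voom fit on recovered reads and a fit without genes that carry certain 3′ UTR motifs were added after the data had been seen.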

Results

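RNA was sequenced from vascular smooth muscle cells, the contractile cells of the vessel wall, which were cultured from mouse aorta. Short interfering RNA (siRNA) against Ezh2 was used in 3 samples (siEzh2) and 3 samples were their controls, all taken at 48 hours. Ezh2 encodes the main methyltransferase of Polycomb repressive complex 2 (PRC2), which places the repressive mark H3K27me3 on chromatin. What the control cells received is not given in the sources used here. The deposited values were read fragments scaled by gene length and library size (FPKM) for 27502 genes. Steps in the low values gave 18248440, 18753125 and 18543978 reads for control samples 1 to 3 and 16080006, 17553744 and 17391245 for siEzh2 samples 1 to 3. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical.

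The comparison asked which transcripts differed after knockdown of Ezh2. Ezh2 itself (ENSMUSG00000029687, chromosome 6 from 47530139 to 47595341 on the minus strand, mm10) had 3.41, 3.59 and 3.88 FPKM in the control samples and 1.20, 1.09 and 1.05 FPKM in the siEzh2 samples. Its mean was 3.63 ± 0.237 (SD, n = 3) in control and 1.11 ± 0.0781 (SD, n = 3) in siEzh2 samples, 3.26 times lower. On the log2(FPKM + 1) scale, which understates changes of low genes, Ezh2 fell by 1.13 (SE 0.0513, adjusted p = 5.15e-05, limma with Benjamini-Hochberg adjustment). With a pseudocount of 0.1 in place of 1 the log2 fold change was −1.62. These values rest on 1347 reads over the 3 control samples and 379 over the 3 siEzh2 samples, and 2.61% of the exon bases of Ezh2 are shared with an antisense gene.

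Most of the other tested subunits of PRC2 were higher or did not pass the test. Of 11 tested members of the PRC2 list, 6 were higher and 2 lower (7 and 2 adjusted over the list alone), and the list had no call by camera (adjusted p = 0.312). Suz12, a core subunit, had 8.33 ± 0.748 FPKM in control and 10.4 ± 0.457 in siEzh2 samples (SD, n = 3 each, log2 fold change 0.30, adjusted p = 0.0122). Ezh1, the paralogous methyltransferase, passed the test with a log2 fold change of 0.22 (adjusted p = 0.0208). It lost the call without any 1 of control samples 2 and 3 or siEzh2 samples 1 and 2 (adjusted p = 0.0614 to 0.0655). Eed, the subunit that binds H3K27me3, had 11.4 ± 0.709 and 11.7 ± 1.26 FPKM (SD, n = 3 each), a difference within the spread between samples (adjusted p = 0.792). Rbbp4, a histone-binding subunit of several complexes, rose by 0.44 on the log2 scale (9.1% of its exon bases overlap an antisense gene and 8.94% Sync), and Epop, an accessory subunit, by 0.38. The other gene that fell was Phf19, an accessory subunit that binds methylated H3K36, which fell by 0.35. Phf19, and Irgm1, Ccne1, Prc1, Tinagl1, Cald1, Acta2, Tagln, Cdkn1a and Cdkn2a in later paragraphs, were chosen after their values were seen.

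**Figure D1:**
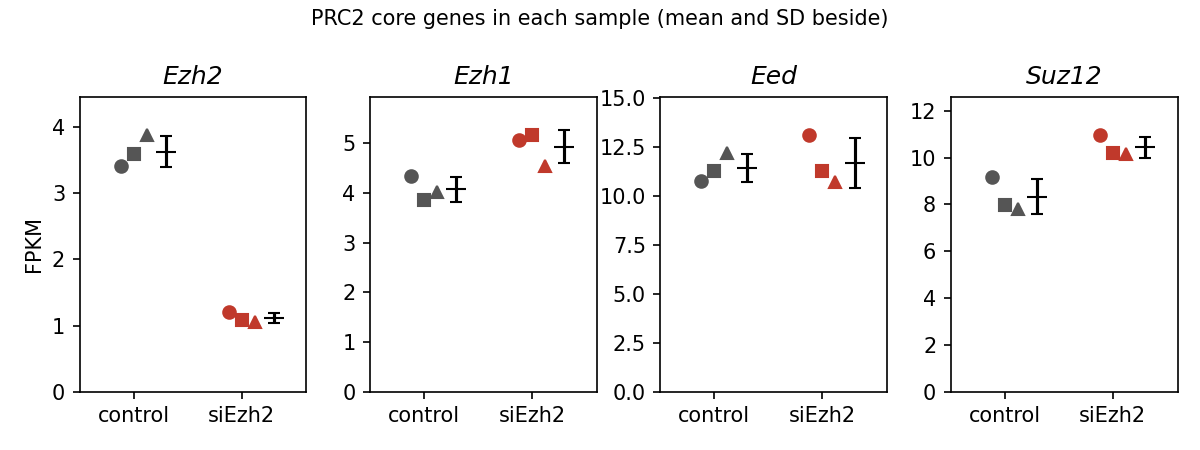
FPKM of Ezh2, Ezh1, Eed and Suz12 in each of the 3 control samples (grey) and 3 siEzh2 samples (red), with circles, squares and triangles for samples 1, 2 and 3 and the mean and SD of each group beside the points. Every siEzh2 sample lies below every control sample for Ezh2 (1.05 to 1.20 against 3.41 to 3.88 FPKM), and the groups overlap for Eed.

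Among called genes with a mean of at least 5 FPKM, predicted genes and pseudogenes left out, the largest rises were in genes of several kinds. Ranks are by the log2 fold change on log2(FPKM + 1). A gene outside the first 12, such as Gdf15 (2.72 times), can therefore have a larger FPKM ratio than one inside. Ctxn1, which encodes the membrane protein cortexin 1 (ENSMUSG00000048644, chromosome 8 from 4257660 to 4259274) rose from 3.36 ± 0.511 to 23.6 ± 2.36 FPKM (SD, n = 3 each), 7.04 times. Taldo1 (ENSMUSG00000025503, chromosome 7 from 141392199 to 141402968), transaldolase of the pentose phosphate pathway, rose from 16.4 ± 0.641 to 68.1 ± 1.35 FPKM (SD, n = 3 each, adjusted p = 2.89e-05). Prl8a9, Prl2c3 and Prl2c2 of the prolactin family rose 4.43, 3.98 and 3.16 times. The last 2 are near-identical copies whose reads the counting could have split between them, so their separate values are uncertain. The remaining 7 of the 12 largest rises were Ivl, which encodes involucrin of the epidermal envelope (4.58 times), the interferon-stimulated genes Bst2 (3.61), Ifit1 (3.35) and Isg15 (2.69), the chemokine Ccl7 (3.56), Gxylt1, which adds xylose to Notch receptors (2.79), and the neuropeptide gene Npy (2.78). Npy had 6.97 ± 1.40 FPKM in control and 19.4 ± 4.34 in siEzh2 samples (SD, n = 3 each, adjusted p = 0.0018).

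Under the same rule, and ranked on the same log2(FPKM + 1) scale rather than by FPKM ratio, the largest falls included genes of the matrix, of growth factors and of contraction. Susd2, a membrane protein with a sushi domain (ENSMUSG00000006342, chromosome 10 from 75636706 to 75644008) fell from 11.6 ± 1.03 to 3.01 ± 0.403 FPKM (SD, n = 3 each, adjusted p = 9.32e-05), and Angptl7, a secreted angiopoietin-like protein (ENSMUSG00000028989, chromosome 4 from 148495183 to 148500460) from 13.2 ± 0.819 to 4.01 ± 0.157 FPKM (SD, n = 3 each, adjusted p = 3.57e-05). Vegfd, a growth factor of lymphatic vessels, fell from 233 ± 4.66 to 104 ± 3.35 FPKM (SD, n = 3 each), and Myl9, the regulatory light chain of smooth muscle myosin, from 154 ± 2.43 to 65.5 ± 0.742 FPKM (SD, n = 3 each). Apln, the ligand apelin, was 3.23 times lower, Pawr, a pro-apoptotic regulator, 2.89, and the sulfotransferase Sult1a1 2.90 (4.05% of its exon bases overlap Sgf29). The other 5 were Ehd3 of endocytic recycling (2.73 times lower), Loxl2, a lysyl oxidase that crosslinks collagen (2.52, with 5.57% of its exon bases in an antisense gene), Dpt, dermatopontin of the matrix (2.42), the membrane protein Tmem37 (2.35) and Aspn, asporin of the matrix (2.34).

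**Figure D2:**
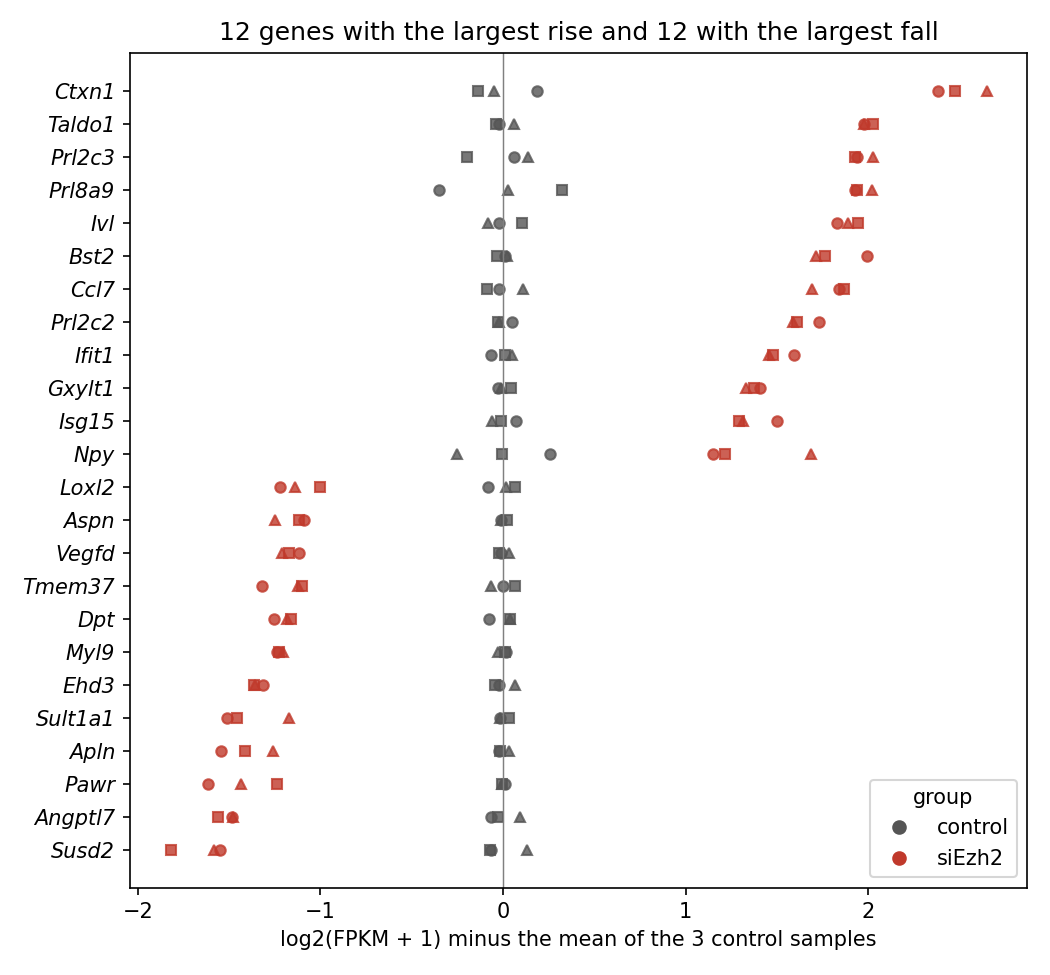
log2(FPKM + 1) of the 12 genes with the largest rise and the 12 with the largest fall on this scale under the naming rule, each sample shown relative to the mean of the 3 control samples of that gene, with control samples in grey and siEzh2 samples in red. Ctxn1 has the largest rise (7.04 times in FPKM) and Susd2 the largest fall (3.84 times), and in none of these genes do the groups overlap.

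Over all 11869 tested genes, 2866 were higher and 2695 lower in siEzh2 samples and 6308 did not pass the test. Most changes were small: the median size among called genes was 0.29 on the log2 scale, and 82 higher and 32 lower genes had a log2 change of at least 1. The median over all tested genes was 0.01. In 6891 genes (58.1%) every siEzh2 sample lay on the same side of every control sample, where chance gives 10%. Correlation across genes, which are not independent replicates, was at least 0.992 between samples of a group and at most 0.980 between groups. Sets of 7-base motifs were chosen after the data had been seen, and not by rank alone. In the motif scan given below, TGTCACG ranked 8 among motifs of the higher genes, while TGTCACT, at rank 3, was left out. CGGAGAA, TCGGAGA or TGTCACG stood in the annotated 3′ UTR of 301 of the higher genes, among 728 tested genes that had such a motif. Ctxn1, Taldo1, Oasl2, Birc5, Slc7a11, Pax1, Hmga2, Vcan and Cald1 were among these. ACATATA or CATATAA stood in the 3′ UTR of 576 of the lower genes (of 1811 tested), with Dpt, Aspn, Loxl2, Ldb3, Acta2, Irgm1, Prc1 and Hoxb4 among them. As the motifs were chosen on these data, more changed genes among their carriers follow in part from the choice. In the scan, 43.1% of genes with CGGAGAA or TCGGAGA in the 3′ UTR were higher. The share was 21.9% of genes with neither there or in the coding sequence. For ACATATA alone, 33.6% were lower, against 23.1% of genes without it in both places. Both kinds of motif also occurred in genes that went the other way, such as Ccl7, Gxylt1, Cxcl5, Col3a1, Slc7a11 and Vcan, which rose with a motif of the lower genes, and Lyz2 and Hoxb4, which fell with a motif of the higher genes.

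Interferon-stimulated genes rose together. Of 44 tested members of this list, 40 were higher, Irgm1 was lower and 3 did not pass (41, 1 and 2 adjusted over the list alone), and the median log2 fold change was 0.74. Oasl2 and Oas2, sensors of double-stranded RNA, rose 3.94 and 3.44 times, to 6.25 ± 0.438 and 7.01 ± 0.353 FPKM (SD, n = 3 each). Bst2, a membrane protein that tethers virions, reached 154 ± 16.1 FPKM from 42.5 ± 0.900 (SD, n = 3 each). The list was higher by camera with a preset correlation of 0.01 (adjusted p = 3.98e-16). The adjusted p was 0.176 with an estimated correlation, which ended the call.

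Chemokines and inflammatory cytokines had 14 higher and 6 lower genes among 23 tested (16 and 6 adjusted over the list alone), with a median log2 fold change of 0.37. Ccl7, which attracts monocytes, rose to 116 ± 7.61 FPKM from 32.6 ± 2.31 (SD, n = 3 each), Cxcl5, which attracts neutrophils, rose 3.23 times and Icam1, an adhesion molecule, 1.52 times (11.7% of its exon bases overlap an antisense gene). The list was called higher (adjusted p = 0.0323), but not without siEzh2 sample 2 (adjusted p = 0.0591), nor with an estimated correlation (adjusted p = 0.414). Markers of macrophages and leukocytes, with 4 tested genes and no list test, moved both ways in the same samples. Lyz2 (lysozyme) and Csf1r, the receptor of macrophage growth factor with 15.1% of its exon bases in Hmgxb3, fell by 1.03 and 0.89 on the log2 scale. Cd14 of monocytes was higher by 0.28 (adjusted p = 0.0375). That call was lost without control sample 2 (adjusted p = 0.0903), control sample 3 (0.0943), siEzh2 sample 1 (0.0882) or siEzh2 sample 3 (0.104), and with quantile normalization (0.0537) or no filter (0.0925).

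Many genes of DNA replication, and some of mitosis, were also higher. In the G1/S and DNA replication list 36 of 46 tested genes rose, Ccne1 (cyclin E1) fell and 9 did not pass (37, 2 and 7 adjusted over the list alone), with a median log2 fold change of 0.28. Cdt1, which licenses replication origins, rose from 5.15 ± 0.229 to 10.2 ± 0.403 FPKM (SD, n = 3 each), the E2F repressor E2f7 1.69 times and Uhrf1, which maintains DNA methylation, 1.36 times. In the G2/M and mitosis list 24 of 50 genes rose and the condensin subunit Smc4 and the spindle protein Prc1 fell (25 and 2 adjusted over the list alone), with a median of 0.16. Birc5 (survivin) rose 1.41 times and Ncapd2, another condensin subunit, 1.36 times. Both lists were called higher (adjusted p = 4.11e-07 and 0.00448), and neither with an estimated correlation (adjusted p = 0.135 and 0.449).

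The antioxidant and ferroptosis list held 19 higher and 8 lower genes among 32 tested, the same counts adjusted over the list alone, with a median log2 fold change of 0.24 (adjusted p = 0.00816). Its adjusted p was 0.176 with an estimated correlation. Slc7a11, the cystine importer, rose from 0.342 ± 0.0287 to 2.67 ± 0.184 FPKM (SD, n = 3 each), and Gclc, which catalyses the rate-limiting step of glutathione synthesis, from 47.1 ± 0.284 to 87.6 ± 0.666 FPKM (SD, n = 3 each). Sod3, the extracellular superoxide dismutase, fell from 74.8 ± 0.256 to 38.7 ± 1.01 FPKM (SD, n = 3 each).

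Contractile genes of smooth muscle fell. Of 28 tested members 21 were lower and 2 higher (the same counts adjusted over the list alone), with a median log2 fold change of −0.28. After Myl9, the smallest p-values were those of Vcl (vinculin), which fell 1.62 times to 40.2 ± 0.528 FPKM with 25.5% of its exon bases in Ap3m1, and Ldb3, a Z-line protein, which fell 2.78 times to 0.514 ± 0.0154 FPKM (SD, n = 3 each). Tinagl1, a matrix protein, and Cald1 (caldesmon) were the 2 that rose. Acta2, smooth muscle actin, fell from 699 ± 14.8 to 537 ± 17.8 FPKM (SD, n = 3 each). Tagln, usually an abundant transcript of smooth muscle, had 0.253 ± 0.0865 FPKM in control and 0.228 ± 0.0744 in siEzh2 samples (SD, n = 3 each), below the filter of the test, and 62.4% of its exon bases also lie in exons of an antisense gene. The list was called lower (adjusted p = 7.45e-06), and had an adjusted p of 0.176 with an estimated correlation.

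Mitochondrially encoded genes, a sign of RNA quality, fell in the same samples as the contractile genes, with 8 of 13 lower, none higher and a median log2 fold change of −0.24 (adjusted p = 0.00491). Adjusted over the list alone, 8 were lower and 0 higher. That call was lost with an estimated correlation (adjusted p = 0.176) and with quantile normalization (adjusted p = 0.0909). Quantile normalization gives each rank 1 value, so mt-Nd1 and mt-Cytb, at the same rank in all 6 samples, had log2 fold changes of 0 there and lost their calls. The call of mt-Co1 was also lost there (adjusted p = 0.0921), with a log2 fold change of −0.31 in place of −0.25. mt-Co1, the most abundant of them, had 7191 ± 64.8 FPKM in control and 6037 ± 151 in siEzh2 samples (SD, n = 3 each). Adipocyte markers had 6 of 9 tested genes lower and none higher (the same adjusted over the list alone), at a median of −0.225 (adjusted p = 0.0195, and adjusted p = 0.242 with an estimated correlation). Among them were Fabp4, a fatty acid carrier, which fell from 19.5 ± 0.208 to 12.6 ± 0.881 FPKM, and Plin4, a lipid droplet protein, from 22.4 ± 0.859 to 15.4 ± 0.363 FPKM (SD, n = 3 each).

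**Figure D3:**
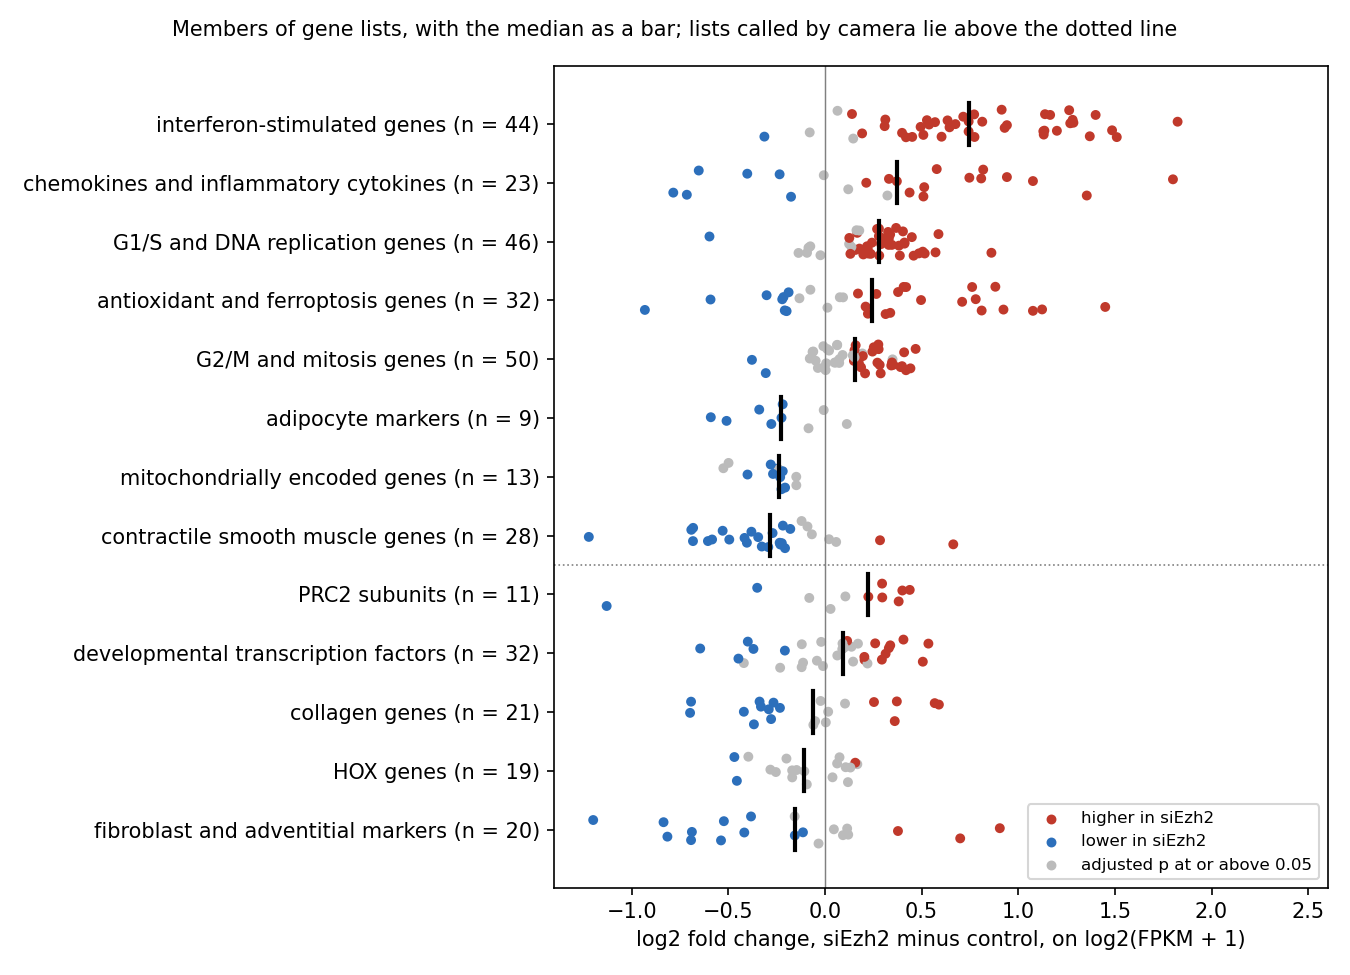
log2 fold changes (siEzh2 minus control, on log2(FPKM + 1)) of the tested members of 13 gene lists, coloured by whether the member was higher (red), lower (blue) or not past an adjusted p of 0.05 (grey), with the median of each list as a bar. The 8 lists above the dotted line were called by camera, from interferon-stimulated genes (median 0.74) to contractile genes (median −0.28), and the 5 below it were not.

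Lists of typical Polycomb targets had no call by camera, while fry, which does not compare a list with other genes, called developmental transcription factors higher (adjusted p = 0.00353) and HOX genes lower (adjusted p = 0.0105). Among 32 tested developmental transcription factors 11 were higher and 5 lower (the same adjusted over the list alone, median log2 fold change 0.09, adjusted p = 0.38). Sox9, a factor of cartilage development, rose from 32.9 ± 0.613 to 47.2 ± 1.22 FPKM (SD, n = 3 each), Pax1 rose 1.58 times and Foxc1 fell 1.35 times. Of 19 tested HOX genes, Hoxb5 and Hoxb4 fell 1.51 and 1.43 times and Hoxb9 passed the test at a log2 fold change of 0.16, while 16 did not pass (adjusted over the list alone, 0 higher and 2 lower; list adjusted p = 0.333). The call of Hoxb9 was lost without control sample 1, 2 or 3 or siEzh2 sample 1 or 2 (adjusted p = 0.0644, 0.086, 0.0645, 0.0779 and 0.085), and with quantile normalization (0.0561), no filter (0.0506) or limma-voom (0.117). Cyclin-dependent kinase inhibitors and senescence genes went both ways, 6 higher and 7 lower of 18 (7 and 7 adjusted over the list alone, list adjusted p = 0.871), and the list's median (−0.07) and mean (0.04) differed in sign. In that list Gdf15, a stress-induced cytokine, rose 2.72 times and the chromatin proteins Hmga2 and Hmga1 rose by 0.76 and 0.59 on the log2 scale. Cdkn2a, which encodes p16 and p19 and is a known Polycomb target, was lower, with a log2 fold change of −0.17 (adjusted p = 0.0339). Cdkn1a, which encodes p21, was higher, with a log2 fold change of 0.21.

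Matrix genes changed in both directions. Collagens had 5 higher and 10 lower of 21 tested (the same adjusted over the list alone, list adjusted p = 0.209). Col3a1 rose 1.52 times, Col5a2 1.49 times, and Col8a1 fell 1.64 times. Elastic fibre and basement membrane genes had 9 higher and 13 lower of 28 (the same adjusted over the list alone, list adjusted p = 0.397). Among them were falls of Eln (elastin), from 22.3 ± 0.950 to 11.7 ± 0.400 FPKM, and of Fbln5 (fibulin 5), from 35.5 ± 0.868 to 18.0 ± 0.635 FPKM, and a rise of Nid1 (nidogen 1), from 274 ± 3.29 to 431 ± 5.82 FPKM (SD, n = 3 each). Synthetic or modulated smooth muscle genes had 13 higher and 8 lower of 28 (14 and 8 adjusted over the list alone, list adjusted p = 0.305), among them Cd44, a hyaluronan receptor, at 2.15 times and Vcan (versican) at 2.21 times its control mean. Fibroblast and adventitial markers had 3 higher and 11 lower of 20 (5 and 11 adjusted over the list alone, list adjusted p = 0.0929). Endothelial markers had 1 higher and 5 lower of 6 (the same adjusted over the list alone, list adjusted p = 0.0929). Endothelial markers below the filter were tested on recovered reads with limma-voom where their mean was at least 3 reads. Of these 8, Vwf and Tek were higher and none lower (log2 fold changes 1.16 and 1.38, adjusted p = 2.46e-10 and 3.53e-05, named after their values were seen).

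The remaining lists of pathways had no call by camera. Among 26 tested p53 targets 12 were higher and 4 lower (12 and 5 adjusted over the list alone, list adjusted p = 0.0956), among them Ei24, whose 3′ UTR holds a motif of the higher genes (log2 fold change 1.06), the kinase gene Plk2 (0.75) and Gdf15 (1.30). Immediate early genes had 10 higher and 6 lower of 21 (10 and 7 adjusted over the list alone, list adjusted p = 0.232), with log2 fold changes of 0.95 for Myc, 0.83 for Junb and 1.06 for Egr3. TGF-beta and BMP pathway genes had 17 higher and 11 lower of 41 (20 and 11 adjusted over the list alone, list adjusted p = 0.312), among them the ligand Tgfb2, which fell by 0.80. Wnt pathway genes had 6 higher and 10 lower of 28 (7 and 10 adjusted over the list alone, list adjusted p = 0.312). Among them the secreted inhibitors Frzb and Sfrp1 fell by 0.97 and 0.66. Below the filter, on recovered reads, the secreted inhibitor Dkk2 was higher and Sfrp4 did not pass (both named after their values were seen). Dkk2 had a limma-voom log2 fold change of 2.33 (adjusted p = 8.185e-05). Glycolysis and hypoxia genes had 14 higher and 3 lower of 29 (16 and 4 adjusted over the list alone, list adjusted p = 0.312), and matrix proteases and their inhibitors 13 and 8 of 29 (14 and 8 adjusted over the list alone, list adjusted p = 0.316).

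Counts of higher and lower genes were 3 and 4 of 19 for PRC1 subunits (list adjusted p = 0.871), 2 and 5 of 13 for the Notch pathway (0.564), 5 and 1 of 13 for osteogenic and chondrogenic genes (0.325) and 6 and 9 of 36 for autophagy (0.333), the same adjusted over the list alone in each. Cholesterol synthesis genes had 9 and 6 of 25 (0.448), heat shock genes 7 and 5 of 19 (0.607), ion channel and calcium handling genes 3 and 9 of 23 (0.209) and pericyte markers 2 and 5 of 8 (0.312), again the same adjusted over the list alone. ER stress genes had 10 and 11 of 33 (11 and 12 adjusted over the list alone), where the median and mean were both 0.04 and camera leaned to lower (0.928). Nuclear-encoded oxidative phosphorylation genes had 2 and 8 of 44 (1 and 6 adjusted over the list alone, 0.129), imprinted genes 4 and 7 of 17 (5 and 7, 0.333) and growth factor and receptor genes 14 and 16 of 41 (15 and 17, 0.718). Ribosomal protein genes, a sign of library composition, had 8 and 4 of 57 (6 and 3 adjusted over the list alone, 0.871). Schwann cell and neuronal markers had 2 and 2 of 7 (the same adjusted over the list alone, 0.95), with a median of 0.03 and a mean of −0.01. Too few genes passed the filter for a list test among epithelial genes (4, with Krt19 higher and Cldn1 lower over all genes, and 2 higher and 1 lower adjusted over the list alone) and skeletal and cardiac muscle genes (1, not past the test), and no germline gene passed it.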

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

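The fits on recovered reads and without motif genes were chosen after the result was seen. Ezh2 stayed lower and called under all 14 alternatives, with log2 fold changes from −1.70 to −1.09 and adjusted p from 7.91e-14 to 0.00231. With an absolute log2 fold change of at least 1, the counts were 82 higher and 32 lower genes instead of 2866 and 2695. All other alternatives gave counts within 1.5 times of these. Quantile normalization gave 2607 and 2891, no filter 2766 and 2383, and a filter of at least 1 recovered CPM in at least 3 samples 3117 and 2870. Trend and robust gave 2877 and 2759, a pseudocount of 0.1 gave 2785 and 2596, and limma-voom 3194 and 3036. Without genes that carry a motif the counts were 2184 and 1978, with 1257 called genes not tested.

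Without single samples, 2309 to 2516 genes were higher and 2156 to 2345 lower, with Ezh2 at −1.16 to −1.09, 4 to 5 lists higher and 3 lower (fewer samples were fitted). Of the 5561 called genes, 4330 to 5428 kept their call and direction in each alternative, except that 4162 did without motif genes. Among the genes of the naming rule, 22 calls were lost and 4 gained over all alternatives, and none reversed.

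The list calls depended on the test. Of 5 lists called higher and 3 lower, an estimated correlation kept 0 and 0, though 6 lists had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 16 and 16. Without a filter 6 lists were higher and 7 lower, and the cause was not tested. Quantile normalization kept 5 and 2.

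With the replicate number as a block, 2564 genes were higher and 2385 lower, Ezh2 was at −1.13 (adjusted p = 0.00231) and 5 and 3 lists were called. Among the genes of the naming rule only Hoxb9 lost its call under the block (adjusted p = 0.0609, 0.0134 to 0.117 over all its alternatives). Same-numbered samples had correlations of 0.0243, 0.0695 and 0.0405 between deviations from their group means, none above 0.1, so the numbers were not used to pair samples. Every sample correlated best with its own number, a hint from the data only.

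The planned count-based tests and their size factors were not run, since the values are FPKM. Depth limits low genes: below the filter, genes such as Tagln were tested only on recovered reads or without a filter.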

Other observations

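The tests of all 7-base motifs, of base composition, of leukocyte markers, of a response to the siRNA duplex, of silencing through seeds and relief from it, of sequencing depth and of Polycomb target release were chosen after the result was seen. The 6 samples allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 2866 higher and 2695 lower genes, and the highest other split gave 0. For higher and for lower genes alike, 1 split, the real one, gave as many.

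Short motifs in 3′ UTRs went with the changes. Among 16069 motifs of 7 bases in 10469 genes, ACATATA had the lowest z (−11.2, 1350 genes with a mean log2 fold change of −0.05), and CGGAGAA (7.89, 270 genes with a mean of 0.17) and TCGGAGA (7.11) the highest. In 0 of 200 shuffles of the fold changes among genes was an absolute z as large as the top one, the highest being 5.45. CATATAA (−7.87) and AACATAT (−5.19) have the same 7 bases as ACATATA but share 6 of them in a row with it, so they mark overlapping sites. With motifs that share 6 bases in a row left out, other orders of the same 7 bases reached absolute z values of at most 3.85 for the lower and 3.56 for the higher motif, under 0.5 of the top values, which argues against base composition as the whole cause. T-rich motifs such as TTTTTTT (6.37) were also beyond the shuffles, so part of the scan reflects something else. When 1 motif was lowered by 0.1 in simulated data on 10469 genes, it ranked 1. That shift was larger than the difference seen for ACATATA (−0.074). Smaller shifts, and motifs as rare as CGGAGAA, were not tried.

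Silencing through the seed of a short RNA acts mostly through 3′ UTRs. To keep the choice of a motif apart from its test, the motif was picked in 1 part of the genes and tested in the rest, and the parts were then exchanged. ACATATA was the lowest both times, and genes with it in the 3′ UTR had lower mean log2 fold changes than genes with it in the coding sequence only, by differences of −0.06 and −0.06 (mean −0.058, two-sided permutation p = 0.034 and 0.022). The highest motif was TCGGAGA in 1 part and TGTCACT in the other, with differences of 0.06 and −0.02 (mean 0.022, permutation p = 0.05 and 0.25), so silencing by an siRNA in control cells stays open. The scan adjusted for the length and base composition of the 3′ UTR and for expression, but these comparisons with coding sequence did not. They therefore cannot separate the place of a motif from such differences between the genes compared. A candidate explanation for the lower motif, not settled by these comparisons, is silencing of some genes by the Ezh2 siRNA. ACATATA also occurs in coding exon 9 of Ezh2 (chromosome 6, 47547410 to 47547416), where CATATAA overlaps it (47547409 to 47547415). However, 11.9% of the single motifs tested occur in the coding sequence of Ezh2, and no such share was computed for overlapping motifs. The siRNA sequences are not given in the sources used here. Motif genes are a part of the changes, since 2184 higher and 1978 lower genes were called without them.

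Interferon-stimulated genes rose with a median of 0.74. Of the 40 higher members, all with an annotated 3′ UTR, 37 had none of CGGAGAA, TCGGAGA and TGTCACG in it, which argues against relief from direct silencing through these motifs as the cause of most of the rise. The other 3 had one, and 6.88% of all tested protein-coding genes did. TGTCACT, another motif of the higher genes, was not counted, so silencing through other motifs was not tested. More leukocytes in siEzh2 cultures were looked for with 11 leukocyte markers, whose median log2 ratio of reads was −0.799 with 9 below 0. That median was Fcgr3, with 21 reads in control and 10 in siEzh2 samples. Among markers with more reads, Csf1r (646 to 183) and Lyz2 (583 to 228) fell, while Cd68 (403 to 444) and Cd14 (262 to 310) rose. No general rise was seen, but the markers went both ways, so more leukocytes stay open. A response to the siRNA duplex and a response to loss of Ezh2 cannot be told apart, since 0 groups had another Ezh2 siRNA or Ezh2 added back. Either may have raised these genes.

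More genes were detected in siEzh2 samples. With every sample thinned to 16080006 reads, the lowest siEzh2 sample still had 719 more genes than the highest control sample, so depth alone does not account for it. A uniform background of reads would give every class of low genes the same gain per kilobase. Low lincRNA genes gained 17 mFPKM (milli-FPKM, 95% bootstrap interval 12.8 to 21.4) and low protein-coding genes 6.71 (5.46 to 7.88), which argues against it. Low processed pseudogenes gained 21.4 (14.6 to 28.2) and low antisense genes 20.9 (16.74 to 25.25). Genes of the annotation class TEC gained 9.1 (6.26 to 12.05), an interval that overlaps that of protein-coding genes. These intervals resample genes, not samples. A larger gain per kilobase was not always a larger fold rise. The ratio of CPM, siEzh2 to control, was 1.128 for low processed pseudogenes, 1.17 for protein-coding, 1.171 for TEC, 1.266 for antisense and 1.285 for lincRNA genes. Low genes were set by a mean of 0.5 to 10 reads whatever their length, which was not corrected for. Low developmental and HOX genes had a median log2 ratio that differed by −0.114 from that of 3362 other low protein-coding genes (48 genes, one-sided permutation p = 0.669), so release of Polycomb targets may or may not contribute and stays open.

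Genes below the filter with a mean of at least 3 recovered reads were tested on these reads with limma-voom. Of 5261 such genes, 280 were higher and 148 lower. Mx1, an interferon-stimulated gene, had 0, 0 and 2 reads in control and 18, 17 and 18 in siEzh2 samples (chosen after its values were seen). Of 38 developmental transcription factors among them, 3 were higher, 1 was lower and 34 did not pass, and these 4 were also named after their values were seen. Sox11, Tfap2c and Tfap2a were higher, with log2 fold changes of 1.27, 1.30 and 0.84. Alx4 was lower, with 7, 2 and 12 reads in control and 0 in each siEzh2 sample. An rRNA gene of chromosome 17 had 2048 FPKM in siEzh2 sample 1 and 929 to 1416 in the other 5.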
